A study of Drosophila melanogaster with 2 samples.

How the data were processed

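The samples were 2 ChIP-seq libraries from whole embryos 0 to 12 hours old of a transgenic Drosophila melanogaster line that expresses CG7745 with GFP at its C-terminus. Per the labels, the description names an antibody against GFP and the antibody field names CG7745 (the description is followed here), chromatin was broken by sonication, the size range was 200 to 800 (with no unit given), and the libraries are biological replicates 2 and 3. The group and the replicate numbers come from those labels, and the 2 libraries come from separate biosamples of 1 fly line.

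The values were used as the authors deposited them. Per the list of files deposited with each sample, peaks were called on each replicate's alignments alone and on both pooled, always against the same control alignment, on genome build dm6, and the IDR set was derived from these 3 lists. The aligner, the peak caller, their versions and the IDR threshold are not given in the sources used here. The signal of each deposited peak is the peak caller's own value against the control, and its scale is not stated. The deposited −log10 q value of a peak runs up to 3.56 in the pooled list, where 1810 peaks share that highest value, so the signal was used to rank peaks. The summit is given by the deposited offset from the peak's start. Because both replicates were called against 1 control, regions that deviate in the control enter both lists alike, so part of their agreement can come from it. The control's own data were not used here.

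Each replicate list and the pooled list holds exactly 30000 peaks, which is a list length and not a depth. Read depth is unknown, so the error given is the exact (Clopper-Pearson) 95% binomial interval over peaks or genes, or the SD over random shifts. All 1874 IDR peaks are in the pooled list and are its 1874 strongest, and 26 of them lie on 13 intervals that appear more than once with different summits. Peaks on the mitochondrial genome were left out of the comparisons.

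Positions were compared with Release 6 of the genome (the assembly known as dm6) and the Ensembl release 115 annotation, which carries FlyBase 6.54, on the 6 main chromosome arms (2L, 2R, 3L, 3R, 4 and X). Mature miRNA products listed as genes of their own and transposable elements were left out. Each summit was given 1 class, the first that applied, in the order promoter (within 500 bp of a protein-coding TSS), 5′ UTR, 3′ UTR, coding exon, intron, other transcribed and intergenic. Chance levels came from 1000 circular shifts of the summits along each chromosome, with two-sided permutation p-values unless stated (smallest possible value 0.002). The shifts cover each whole arm, also stretches where no list holds a peak. On 3L, for example, no peak ends past position 23102632 of 28110227. A gene was called bound when an IDR summit lay within 500 bp of any of its TSS. Gene lists with at least 5 members were tested with Fisher's exact test, older gene names were matched through the reference's synonyms, and 6 list entries had no match. Sequences were searched on both strands in 101 bp windows centred on the summit and in control windows 500 bp away on a random side, with an exact test of discordant pairs. P-values were adjusted by the Benjamini-Hochberg method within each family (7 classes, 6 arms, 34 lists, 2080 6-mers and 24 consensus sequences).

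The tests, the 34 gene lists, the 24 consensus sequences and the rule for named genes were fixed before the data were examined. The rule takes the genes at the 25 strongest IDR peaks at promoters, up to 4 bound members with the highest signal of each list that passed and of each patterning list, CG7745, and the 5 strongest peaks outside promoters. Further genes are named only where a sentence says why or gives a count. Alternatives were other distances and numbers of peaks for the overlap, the upper part of the IDR set by signal, the strongest peaks of each replicate alone, promoter windows of 250 and 1000 bp, summit windows of 30 and 100 bp to each side, other chance levels and other control windows.

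The code was tested on simulated data. With a 6-mer written into 200 summit windows, that 6-mer ranked 1 of all; with lists made to share 60% of summits, 60% were found (60.03%); and with 600 peaks at promoters, 30 of them of ribosomal protein genes, 4 lists were called by Fisher's test, that list among them. In 20 sets of random peaks, the 6-mer test called nothing in any, the promoter test called 1 set, and Fisher's test of gene lists called at least 1 list in 6 sets. The lists so called were Notch pathway and E(spl), cytochrome P450, germline, long noncoding RNA, and snoRNA and snRNA genes. The tools were Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.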

Results

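Chromatin bound by the CG7745 protein was mapped in whole Drosophila melanogaster embryos aged 0 to 12 hours. The method was ChIP-seq, in which DNA crosslinked to a protein is recovered with an antibody, sequenced and searched for peaks. The flies carried a transgene of CG7745 joined at its C-terminus to green fluorescent protein (GFP), and the antibody recognised GFP, per the description in the labels, while their antibody field names CG7745. The labels put both samples, biological replicates 2 and 3, in 1 group and name no second condition (n = 2). The design therefore implies comparisons between the replicates, and between the peaks and the rest of the genome (build dm6). Each replicate's own list held 30000 peaks, as did the list called on both replicates pooled. The reproducible set, chosen by the irreproducible discovery rate (IDR), held 1874 peaks on 1861 distinct intervals, with a median width of 396 bp. The files give no read counts, so the sequencing depth is unknown and intervals below cover the counting of peaks or genes only. The signal of the IDR peaks, the authors' value with no stated scale, ran from 122 to 4752 with a median of 168, and it was used here to rank peaks within a list and to correlate the replicates' matched peaks.

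The replicates placed their strongest peaks at the same sites. The promoter of egr, which encodes the fly tumour necrosis factor ligand Eiger, held the top nuclear peak of both replicates, and the promoter of Socs16D, a suppressor of cytokine signalling gene, held the next in both. The peak beside the noncoding gene lncRNA:CR44366 ranked 3 in both lists, and the peak in an intron of htl, a fibroblast growth factor receptor gene, ranked 4 in both. Of the 100 strongest nuclear peaks of replicate 2, 80 (80%, exact 95% interval 70.8 to 87.3%) had a summit within 100 bp of one among the 100 strongest of replicate 3. Of the 1874 strongest, 1062 did (56.7%, interval 54.4 to 58.9%), against 0.297% after circular shifts of replicate 3's peaks (one-sided permutation p = 0.001, the smallest that 1000 shifts can give). Over all 29981 nuclear peaks of replicate 2 and as many of replicate 3, the shared part was 32.7%, against 4.55% by chance. The agreement was not even among the genes named here: the peak at pan, on chromosome 4, ranked 320 in replicate 2 and 10837 in replicate 3, and the peak at kis had no replicate 2 summit within 100 bp.

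Across the 1764 IDR peaks matched in both lists, Spearman's rho between the replicates' signals was 0.543 and Pearson's r on the log2 scale was 0.69 (permutation p = 1e-05 for each, the smallest that 100000 permutations can give). This is a relation across peaks, which are not independent replicates, and the IDR peaks are the strongest 1874 of the pooled list. Among the 28126 weaker peaks of the pooled list, 8126 were matched in both replicates, with a rho of 0.294.

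**Figure D1:**
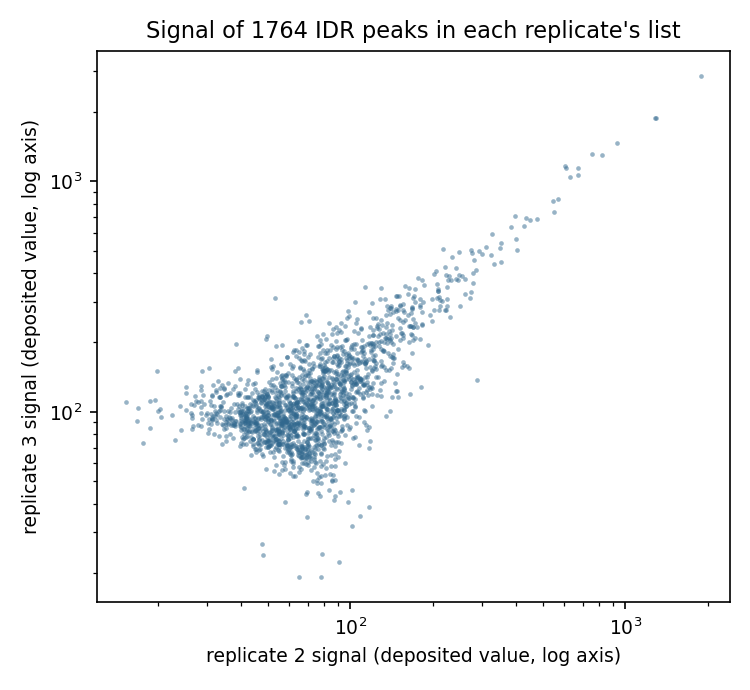
Signal of the IDR peaks in replicate 2's list (x axis, deposited signal, log scale) and in replicate 3's list (y axis, the same), 1 point for each of the 1764 peaks matched in both lists within 100 bp. The strongest peaks lie on a narrow diagonal and the weaker ones spread widely, with a Spearman's rho of 0.543 over all points.

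Promoters and introns held most IDR summits in about equal parts, promoters far above chance, and coding exons outside promoters held almost none. In all, 733 summits (39.1%, exact 95% interval 36.9 to 41.4%) lay within 500 bp of the transcription start site (TSS) of a protein-coding gene, 3.41 times the 11.5% found after circular shifts (SD 0.91, two-sided permutation p = 0.002, the smallest that 1000 shifts can give). A single summit, at position 21053221 of chromosome X in Stt3A, which encodes a subunit of the oligosaccharyltransferase, fell in a coding exon outside promoters. That is 0.0534% of summits (interval 0.00135 to 0.297%), against 13.2% by chance. Summits were also scarcer than chance in 3′ UTRs (1.17 against 5.02%) and in intergenic DNA (17.6 against 28.6%), each with an adjusted p of 0.0035. Introns held 713 summits (38%, against 38.9% by chance, adjusted permutation p = 0.636), and 5′ UTRs 16 (0.854 against 0.769%, adjusted p = 0.723). Noncoding genes outside protein-coding ones held 59 (3.15 against 2.01%, adjusted permutation p = 0.014). The adjusted values in this paragraph are permutation p-values after the Benjamini-Hochberg method over the 7 classes, and the promoter value of 0.002 is not adjusted.

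**Figure D2:**
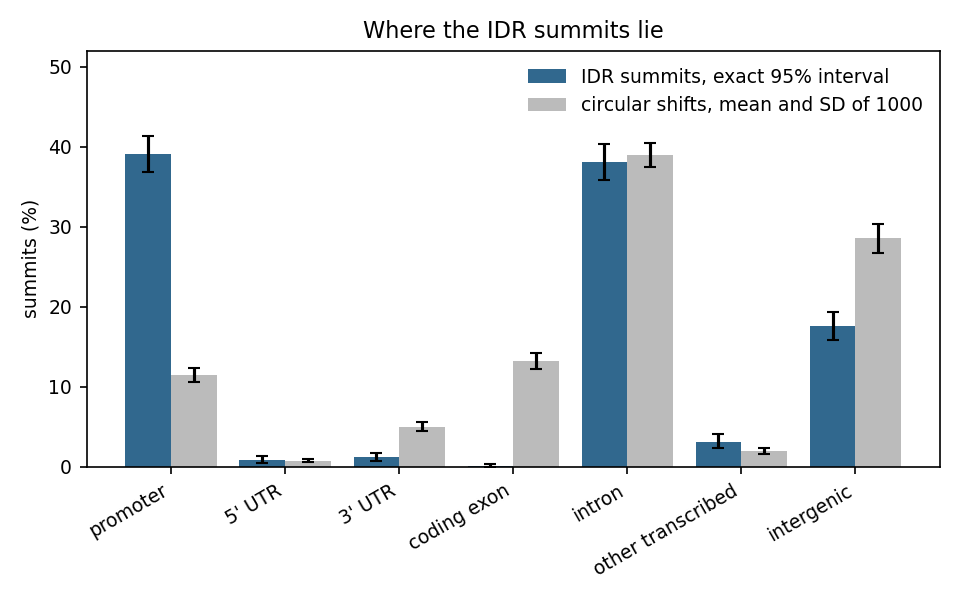
Percent of the 1874 IDR summits in each annotation class (dark bars, with exact 95% intervals) and mean percent after 1000 circular shifts (grey bars, with SD). The dark bar exceeds the grey one most at promoters (39.1 against 11.5%) and is nearly absent for coding exons (0.0534 against 13.2%).

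The scarcity in coding exons was greatest among the strong peaks and lessened with rank. Below the IDR set, coding exons held 7.38% of pooled summits, against 13.2% by chance (adjusted permutation p = 0.0028). In the pooled list, coding exons held 0.352% of summits at ranks 1875 to 5000, 1.74% at ranks 5001 to 10000, 7.19% at ranks 10001 to 20000 and 12.6% at ranks 20001 to 30000. Over the same ranks the promoter class fell from 38.5% to 19.4%. The intergenic share changed little, from 18% at ranks 1 to 200 to 19.55% at ranks 20001 to 30000. Below the IDR set it was 19.8%, against 28.1% by chance (adjusted permutation p = 0.0028). The intergenic deficit was thus not particular to the IDR set, and its chance level also covers stretches where no list holds a peak.

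**Figure D3:**
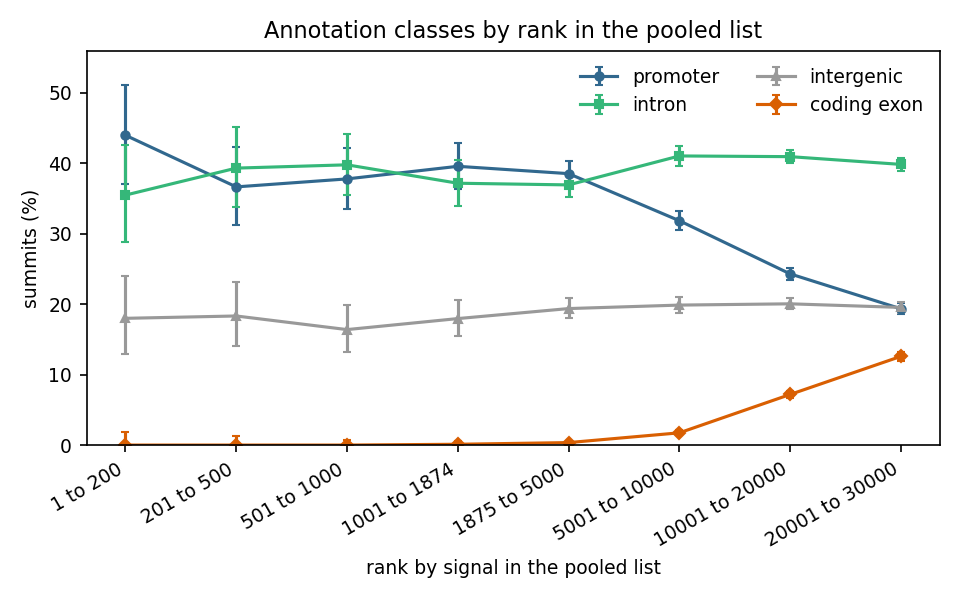
Percent of summits (y axis) in 4 annotation classes by rank of signal in the pooled list (x axis), with exact 95% intervals. Promoters go from 44% at ranks 1 to 200 down to 19.4% at ranks 20001 to 30000, while coding exons go from 0% to 12.6%.

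At promoters the summits lay mostly upstream of the TSS. Of those not exactly on a TSS, 494 were upstream (67.8%, exact 95% interval 64.2 to 71.1%, two-sided exact binomial p = 4.5e-22), and the median position was -73 bp (quartiles -172 and 26 bp). Genes with a head-to-head neighbour were bound more often than others: 477 of 5052 protein-coding genes with an opposite-strand TSS within 1000 bp (9.44%), against 404 of 8893 without (4.54%), an odds ratio of 2.19 (two-sided Fisher's exact p = 5.76e-29). A shared promoter counts for both of its genes there. With each pair counted once, 313 of 2667 head-to-head pairs (11.7%) had either gene bound. With each promoter base and each summit counted once, promoter windows of such genes held 69.5 summits per Mb and those of other genes 38.7. This count was added after seeing the data (ratio 1.80, exact binomial p = 1.39e-14). Bases between paired genes lie near both TSS, so the ratio does not show more binding per TSS.

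Chromosome X was under-represented among the IDR peaks. It held 177 IDR peaks (9.45%, exact 95% interval 8.16 to 10.9%), against 17% of protein-coding TSS positions (exact binomial test, adjusted p = 5.9e-20 over 6 chromosome arms). Arms 3L (433 peaks, ratio 1.19, exact binomial adjusted p = 0.000161) and 2L (412 peaks, ratio 1.17, adjusted p = 0.00121) held more than their part, while 2R, 3R and the small chromosome 4 (404, 434 and 14 peaks) did not pass the test. In the whole pooled list, X held 14.9% of peaks, also below its part of TSS positions (ratio 0.876, exact binomial adjusted p = 1.35e-22). By rank it held 10% at ranks 1 to 200, 12.9% at ranks 1875 to 5000 and 17.2% at ranks 20001 to 30000. The low part of X was thus a trait of the stronger peaks, and its cause was not tested. Repeat-masked bases made up 21.7% of the summit windows, against 20% by chance (SD 0.927, permutation p = 0.0759). The shifts also place summits in stretches where no list holds a peak. This comparison therefore does not settle whether summits hold more repeats than the sequence in which peaks were found.

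The strongest promoter peaks lay at genes of many kinds. The egr peak (FBgn0033483, chromosome 2R, 10077317 to 10078586) had a signal of 4752 with its summit at -142 bp, upstream of the TSS. The Socs16D peak (FBgn0030869, X, 17826721 to 17827775) had a signal of 3195 at 349 bp downstream of a TSS. The next were chic, which encodes the actin-binding protein profilin (FBgn0000308, 2L, 5979796 to 5981243, signal 2129.9, -208 bp), CG12107 (FBgn0033209, 2R, 7674170 to 7674785, signal 2065, 12 bp), mrva (FBgn0035763, 3L, 7328458 to 7329200, signal 1768, 38 bp) and CG9917 (FBgn0030740, X, 16322904 to 16323444, signal 1396, 70 bp). The CG12107 peak also lies at the start of mRpL52, a mitochondrial ribosomal protein gene, at -62 bp from its TSS. These 6 peaks ranked 1, 2, 5, 6, 8 and 12 in the IDR set.

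Further down this group, with signals between 1265 and 604, came Ifrd1, Cpsf5 (a pre-mRNA 3′ end processing factor), Spn42De (a serpin), Myo61F (a class I myosin), px, Arl5 (a small GTPase), ph-p (a Polycomb group protein), Patsas, mRpS10 (of the mitochondrial ribosome), CG14100, ric8a, fry, Atxn7, her (a sex determination regulator), CG1888, CG18549, CG31688, Fkbp14 and Arp10. Of the 25 genes at the strongest promoter peaks, ph-p had a signal of 897.6 at -481 bp, mRpS10 861 at -127 bp, fry 788 at -5 bp and her 737 at 5 bp. All 25 peaks had a matched summit among the 73 strongest nuclear peaks of each replicate.

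The strongest peaks outside promoters lay on chromosomes 2R, 3R and 3L. The strongest (2R, 13577309 to 13578241, signal 3129) was intergenic, upstream of the nearest protein-coding TSS, that of CG42808 (distance -3624 bp), and close upstream of the TSS of lncRNA:CR44366 (distance -155 bp). The next was in an htl intron (3R, 18049851 to 18050521, signal 2399), at -839 bp from the nearest TSS. The others lay in introns of CG42671 (3L, 11224681 to 11225224, signal 1821), of Sarm (3L, 8065436 to 8066333, signal 1763) and of CG45088 and CG6191 (2R, 13583979 to 13585202, signal 1719). The Sarm peak, in a gene for a Toll/interleukin-1 receptor domain adaptor, sits beside tRNA:Leu-CAG-1-5, with its summit at -77 bp from that tRNA gene's start.

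Of 13945 protein-coding genes, 881 (6.32%) had an IDR summit within 500 bp of a TSS. Genes of cytoplasmic ribosomal proteins were bound far more often than other genes, and genes for sensory receptors and cuticle proteins far less often. Among 34 gene lists, 9 were bound more often and 5 less often than their background (two-sided Fisher's exact test, adjusted p under 0.05 over the lists). Neighbouring genes can share a peak, and in 6 of 20 sets of random peaks this test called at least 1 list. Those peaks were placed uniformly, while IDR summits lay closer together, so that rate may not carry over. Each call is therefore given with its adjusted p from shifts of the bound flags along gene order. Those shifts called no list in any of the 20 sets, which says little about their false calls. Fewer shifts were run there than in the main test, so the smallest possible p was higher. In the main test their permutation p cannot fall below 0.002, and 1 list alone at that value stays above 0.05 after adjustment over 34 lists. The adjusted p of 0.0113 given below belongs to lists at that smallest value.

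Among ribosomal proteins, 37 of 92 genes were bound (40.2%, exact 95% interval 30.1 to 51%), against 6.09% of other protein-coding genes (odds ratio 10.4, adjusted p = 1.72e-19, and adjusted p = 0.0113 with gene-order shifts). The strongest were RpL7 (signal 276, 18 bp), RpS4 (signal 272, -5 bp), RpS27 (signal 269.9, -20 bp) and RpL13 (signal 262, 5 bp), which ranked 290, 305, 312 and 338 in the IDR set. Translation factors had 8 of 54 genes bound (Fisher's adjusted p = 0.0468), with eIF4EHP at signal 292, eEF1gamma at 218, eIF4E1 at 179 and eIF1 at 154, whose peak is the one counted for RpL28. That call was lost with gene-order shifts (adjusted permutation p = 0.0962) and with either replicate left out (adjusted p = 0.0557 and 0.673), and the eIF4EHP peak had no summit in replicate 3 within 100 bp. Other housekeeping lists did not pass Fisher's test: 8 of 73 mitochondrial ribosomal protein genes (adjusted p = 0.208), 4 of 32 splicing factor genes (adjusted p = 0.208), 3 of 46 replication and cell cycle genes (adjusted p = 0.84), 4 of 90 oxidative phosphorylation genes (adjusted p = 0.776), 4 of 82 transcription machinery genes (adjusted p = 0.87) and 1 of 48 proteasome genes (adjusted p = 0.501). With the upper 937 IDR peaks alone, mitochondrial ribosomal protein genes did pass (9.59% bound, Fisher's adjusted p = 0.035).

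Several developmental lists were bound more often. In dorsal-ventral patterning, 10 of 31 genes were bound (32.3%, odds ratio 7.13, Fisher's adjusted p = 0.000143, and adjusted p = 0.0113 with gene-order shifts), led by shn (signal 472), a transcription factor of BMP signalling, htl (242), stumps (232), which acts with Htl, and the GATA factor gene pnr (229.7). In the Notch pathway and E(spl) list, 8 of 25 were bound (32%, odds ratio 7.03, Fisher's adjusted p = 0.000688, and adjusted p = 0.0291 with gene-order shifts), led by E(spl)mdelta-HLH (signal 249.9), E(spl)m7-HLH (238), the ubiquitin ligase gene neur (198) and the kinase gene aPKC (174). In the gut and endoderm list, 5 of 16 were bound (31.3%, Fisher's adjusted p = 0.00822, and adjusted p = 0.0377 with gene-order shifts), led by bowl (361), the forkhead factor gene fkh (211), the ETS factor gene pnt (155) and the homeobox gene Dr (151). With the upper 937 IDR peaks alone, the gut and endoderm call was lost (Fisher's adjusted p = 0.211). These calls are not independent, because the lists share members. The neur peak counted for the dorsal-ventral and Notch lists, and the Dr peak for the dorsal-ventral and gut lists. The bound E(spl) genes lie close together on 3R, between positions 25997621 and 26038019. The Notch list was also among those that Fisher's test called in random peaks.

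Segment polarity genes (4 of 15), architectural and insulator protein genes (5 of 20) and Polycomb and Trithorax genes (6 of 30) passed Fisher's test, with adjusted p-values of 0.0322, 0.0215 and 0.0285. None of the 3 passed with gene-order shifts (adjusted permutation p = 0.11, 0.0926 and 0.0747). Their bound members included ptc, nkd, ci and pan (signals 186, 177, 148 and 135), Chro, Dref, Cp190 and lola (539, 262, 253 and 225), and ph-p, kis, Su(z)2 and E(z) (897.6, 221, 196 and 194). The Dref and RpL13 values come from 1 shared peak. Of the other patterning lists, pair-rule genes had 3 of 13 bound (bowl, odd and hry, at 361, 154 and 124, Fisher's adjusted p = 0.0893), Hox genes 1 of 8 (abd-A, 154, adjusted p = 0.532) and gap and maternal genes 1 of 14 (Kr, 159, adjusted p = 0.728). Without replicate 3, pair-rule genes passed (30.8% bound, Fisher's adjusted p = 0.0178), as did proneural and neuroblast genes (24.1%, adjusted p = 0.00626).

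Lists of receptor and cuticle protein genes were bound less often. Chemoreceptor genes, including odorant-binding proteins, had 2 of 230 bound (Obp46a and Obp99b, signals 172 and 167, Fisher's adjusted p = 0.000688, and adjusted p = 0.0113 with gene-order shifts). None of 122 cuticle protein genes was bound (exact upper limit 2.98%, adjusted p = 0.00272, and adjusted p = 0.0113 with gene-order shifts). The cuticle call was lost with the upper 937 IDR peaks alone (Fisher's adjusted p = 0.109). The 111 histone genes also had none (upper limit 3.27%, Fisher's adjusted p = 0.0048), but they lie in 1 repeated cluster and the shifts gave an adjusted p of 0.131. How reads that match several copies were handled is not given. A lack of peaks there therefore cannot be told from a lack of placed reads.

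Among noncoding genes, 33 of 290 tRNA genes were bound (11.4%, odds ratio 2.14, Fisher's adjusted p = 0.00101, and adjusted p = 0.034 with gene-order shifts), from 22 distinct peaks, of which those at 9 of the genes also lay at a protein-coding promoter. The strongest were tRNA:Leu-CAG-1-5 and tRNA:Leu-CAG-1-6, which share the Sarm peak (signal 1763), tRNA:Val-CAC-1-1 (507) and tRNA:Gly-TCC-2-2 (327). Long noncoding RNA genes (79 of 2520, Fisher's adjusted p = 1.33e-09) and miRNA genes (4 of 260, adjusted p = 0.0048) were bound less often than other genes, each with an adjusted p of 0.0113 with gene-order shifts. The miRNA call was lost with a promoter window of 1000 bp (Fisher's adjusted p = 0.0874). The strongest of the long noncoding RNA genes were lncRNA:CR44366 (3129), asRNA:CR44982 (774), lncRNA:CR31840 (764) and lncRNA:CR31044 (663), and the 4 miRNA genes were mir-9378 (398), mir-4918 (138), mir-9377 (137) and mir-9374 (123). The asRNA:CR44982 peak is the one named above at the Atxn7 promoter.

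**Figure D4:**
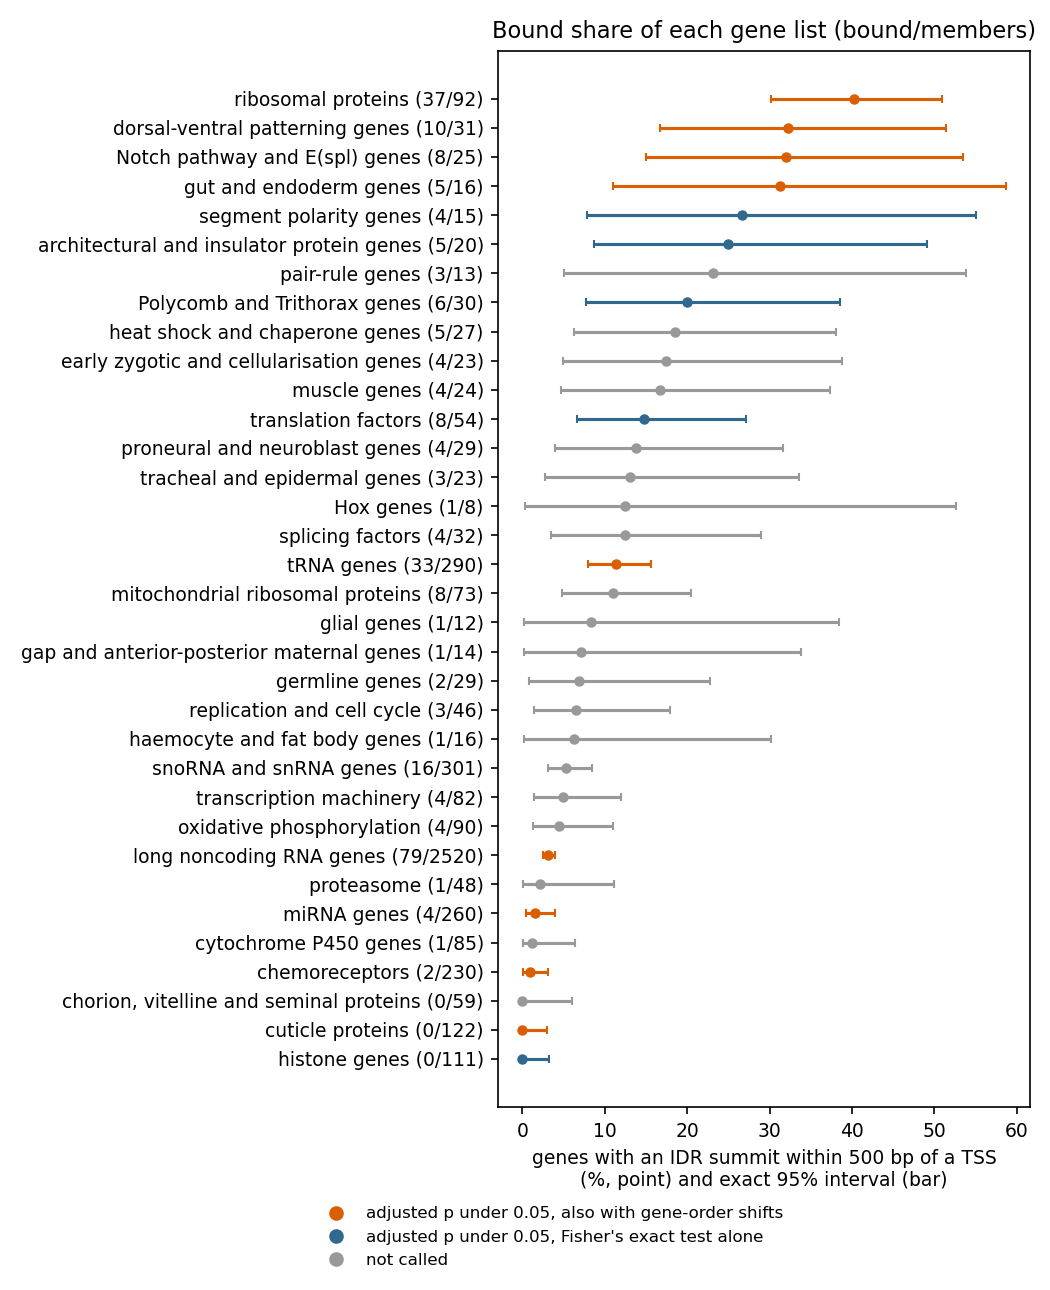
Percent of each list's genes with an IDR summit within 500 bp of a TSS (x axis), with exact 95% intervals, for 34 gene lists (y axis, bound and total members in brackets), coloured by whether the list passed the tests. Ribosomal proteins stand highest at 40.2%, and 4 developmental or ribosomal lists pass with gene-order shifts above 30%.

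Sequences rich in A and T with an ATTA core marked the summits. AATTAA occurred in 598 of 1874 summit windows of 101 bp (31.9%), against 309 control windows 500 bp away (16.5%), a ratio of 1.94 (two-sided exact paired test, adjusted p = 3.75e-26 over 2080 6-mers). AAATTA occurred in 31.3 against 15.7% (ratio 1.99, exact paired test, adjusted p = 3.15e-26) and TAATTA, a core recognised by many homeodomain proteins, in 17.8 against 7.9% (ratio 2.25, adjusted p = 4.87e-16). In the 100 strongest peaks AATTAA was present in 60 summit windows (60%, exact 95% interval 49.7 to 69.7%) and 16 control windows, and at ranks 1001 to 1874 in 26.4% (23.5 to 29.5%). In all, 88 6-mers were more frequent at summits, 18 of them of A and T alone, and 101 less frequent, of which none was of A and T alone. These counts depend on the setting: 49 and 46 of the 88 and 49 and 31 of the 101 were called again without replicate 2 and without replicate 3, and 6 and 1 against unbound promoters. GGAGGA had the lowest p-value among the less frequent 6-mers, with 24 summit windows against 107 controls (exact paired test, adjusted p = 3.26e-11). It was not called at promoter summits against unbound promoters. The 6-mers named here are those with the 4 lowest p-values, a choice made after their values were seen.

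**Figure D5:**
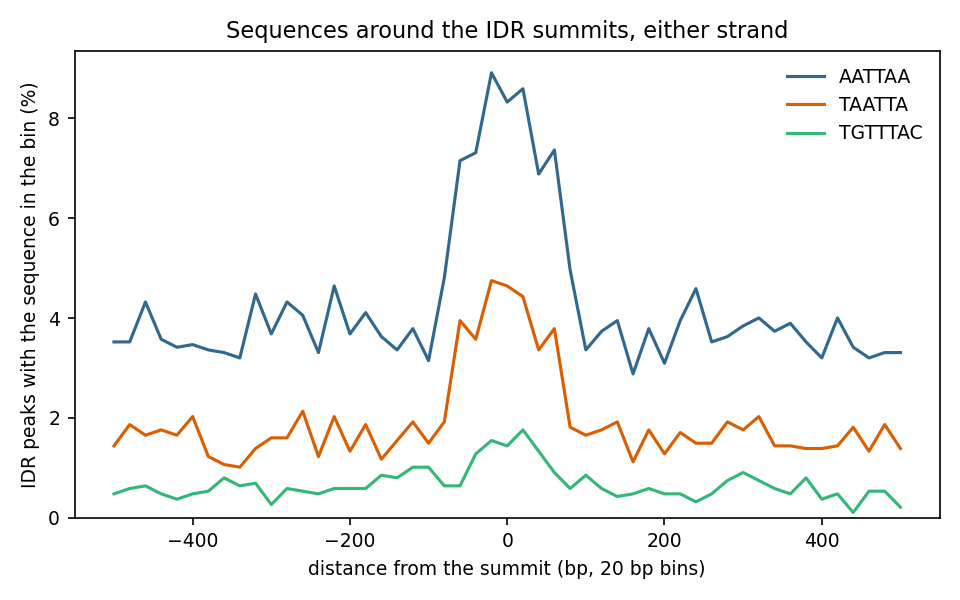
Percent of the 1874 IDR peaks (y axis) with AATTAA, TAATTA or the forkhead consensus TGTTTAC on either strand in each 20 bp bin, by distance from the summit in bp (x axis). AATTAA is at 8.32% in the central bin against 3.52% in the bin at -500 bp, and TAATTA 4.64 against 1.44%.

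Of 24 known consensus sequences, 9 were more frequent at summits and 1 less frequent. Beside the homeodomain core, the forkhead consensus TGTTTAC stood at 6.72 against 2.45% of windows (exact paired test, adjusted p = 4.78e-09), Motif 1, the core promoter element bound by M1BP (GGTCACAC), at 1.28 against 0.107% (adjusted p = 8.39e-05), and the GAGA factor site at 4.91 against 2.29% (adjusted p = 0.000134). Against unbound promoters, promoter summits kept the homeodomain and GAGA calls only: Motif 1 stood at 3.14 against 2.73% (exact paired test, adjusted p = 1) and the forkhead consensus at 5.59 against 3.14% (adjusted p = 0.133). The GAGA call was lost with the upper 937 IDR peaks (4.06 against 2.35%, exact paired test, adjusted p = 0.156) and with windows of 30 bp to each side (2.4 against 1.71%, adjusted p = 0.401). The DRE (TATCGATA, 1.44 against 0.374%, exact paired test, adjusted p = 0.00391), the Su(Hw) site (TTGCATAC, 0.747 against 0.0534%, adjusted p = 0.00391), the CTCF core (AGRKGGCGC, 9 windows against 0, adjusted p = 0.0134), the GATA site (2.19 against 1.17%, adjusted p = 0.045) and Ohler motif 6 (GTATWTTT, 3.58 against 2.24%, adjusted p = 0.045) also passed, and the Runt site was less frequent (2.83 against 4.43%, adjusted p = 0.0359). These last 6 calls were lost with the peaks of either replicate alone, where the Su(Hw) site stood at 16 windows against 5 in each and the CTCF core at 9 against 3 and 11 against 2. The DRE stood at 18 against 5 without replicate 2 and at 19 against 10 without replicate 3. The site of Zelda, the activator of the early zygotic genome, stood at 10 against 18 windows (exact paired test, adjusted p = 0.341). Its direction depended on the replicate, with 10 against 13 windows without replicate 2 and 16 against 9 without replicate 3.

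At the gene of the tagged protein itself, CG7745 (FBgn0033616, chromosome 2R, 11307879 to 11309829, forward strand), no IDR peak lay within 2000 bp. The pooled list held 6 peaks there, the strongest at rank 3302 (11307060 to 11307455, signal 94.1), below the lowest IDR signal of 122. Replicate 2's list held 5, the best at rank 1048, and replicate 3's held 7, the best at rank 2400. The tagged copy is a transgene, so its site does not test the labels.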

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

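Replicate 2's list held 19 peaks on the mitochondrial genome, which the comparisons above leave out. They made up 15 of the 20 strongest peaks of that list, with signals from 83.9 to 6952, the highest at mitochondrial positions 10445 to 11132, and the strongest nuclear peak ranked 12. Replicate 3's list and the pooled list held 0 such peaks. This drew attention because it is a strong signal in data outside the main measurement, seen in 1 replicate of 2; no explanation was tested.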

How the results depend on the processing

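The settings that asked for the nearest gene at any distance, 1 TSS per gene, GC-matched control windows, each promoter base counted once, the other replicate's whole list and the weaker pooled peaks were chosen after seeing the data. The planned use of the 1874 strongest pooled peaks gave the IDR set itself and tests nothing. Leaving it aside, 66 recomputed main values kept their direction and their side of the threshold or, for counts, stayed within 1.5 times, 28 counts moved, 1 value passed the threshold and 1 turned (introns below the IDR set, 40.1%, not past the threshold in either). Those that kept include every value for replicate overlap, replicate rank agreement, promoter share, coding exons, summit position, divergent promoters and chromosome X. Without replicate 2 or 3, for example, the promoter share was 40.1 to 40.2% and the X share 8.86 to 9.39%. Repeat content rose past the threshold in the upper part of the IDR set (22.7%, permutation p = 0.02).

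Of the gene lists, 5 were bound more often with gene-order shifts and 4 with the nearest gene at any distance, against 9, and 3 were bound less often in the upper part of the IDR set and 1 with the nearest gene, against 5. The nearest-gene setting tested 30 of the 34 lists, without the tRNA, miRNA and long noncoding RNA calls, so its counts are not fully comparable. Cuticle proteins lost their call there (3 summits against 7.81 by chance, adjusted permutation p = 0.377) and in the upper part of the IDR set. Ribosomal proteins, dorsal-ventral patterning, Notch pathway, chemoreceptor, tRNA and long noncoding RNA genes were called in the same direction in all 7 alternatives other than the nearest gene at any distance.

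The 88 more and 101 less frequent 6-mers became 56 and 31 in the upper part of the IDR set, 39 and 14 outside promoters, 58 and 35 with 30 bp windows, 134 and 170 with 100 bp windows, and 6 and 2 at promoters against unbound promoters. With GC-matched controls 67 were more and 51 less frequent, and 51 of the 88 and 25 of the 101 were kept. Without replicate 2 or 3 they were 51 to 67 and 56 to 95. AATTAA, AAATTA and TAATTA kept an adjusted p under 0.05 in all of these. The cause was not tested.

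The 9 more frequent consensus sequences became 4 without replicate 2 or 3 and with 30 bp windows, 3 outside promoters and 2 against unbound promoters, and only the homeodomain core passed in all of these. The 1 less frequent one became 0 in each of these and with 100 bp windows. Some turned, without passing the test: Runt without replicate 3 (2.88 to 3.68% of summits without replicate 2 or 3), DRE (0.175%) outside promoters, and the CTCF core (0%) and GATA (1.77%) against unbound promoters. Motif 1 became equal outside promoters (0.0876% of summits and of controls). The cause was not tested. Among named lists, sequences and lesser classes, 278 recomputed values kept their call, 52 lost it, 8 gained one and 26 turned. Lists that gained a call in some setting were mitochondrial ribosomal proteins, pair-rule, proneural and heat shock genes, and, after turning, snoRNA and snRNA genes. Read depth is unknown, so what it limits cannot be stated.

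The other values that turned had not passed the test, and only snoRNA and snRNA genes passed after turning (12.6% with a promoter window of 1000 bp; with 1 TSS per gene 5.32%, not passed). In the upper part of the IDR set they were arm 3R (23.7%) and replication (2.17%), Hox (0%), gap and maternal (0%), glial (0%) and germline (0%) genes. Without replicate 2 or 3 they were 5′ UTRs (0.747 to 0.800%), arms 2R (20.4 to 21.8%) and 3R (23.1 to 24.6%), and haemocyte (6.25% in both), tracheal (4.35 to 17.4%) and germline (0 to 10.3%) genes. By chromosome length it was chromosome 4 (0.747%). With a promoter window of 250 bp they were replication (4.35%) and haemocyte (6.25%) genes, with 1000 bp replication (6.52%), gap and maternal (7.14%) and germline (6.9%) genes, and with 1 TSS per gene replication (4.35%) and early zygotic (4.35%) genes.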

Other observations

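The values in this part were chosen for description after the results were seen, as were the tests of signal against AATTAA, of the weakest pooled peaks and of the other housekeeping lists. The tests with GC-matched windows, with GC-matched positions and of AATTAA at ribosomal protein promoters were set before their results were seen.

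IDR summits lay closer together than under uniform placement. Of 1868 neighbouring pairs on a chromosome, 477 lay within 5000 bp (25.5%), against 7.11% with uniform placement (permutation p = 0.002, the smallest that 1000 draws can give). The 26 peaks on shared intervals add to these close pairs. Uniform placement takes no account of where genes lie, and 39.1% of summits lay at promoters. The comparison therefore does not show clustering beyond that of genes. Among protein-coding genes with the 5000 bp before them, Eip75B, fz2 and jing held 10 summits each, CG1677, sbb and ush 9 each, bun and osp 8 each, and Btk, CG5953, EcR, PRAS40, px, shn and tkv 7 each. Long genes have more room for summits: Eip75B spans 114 kb and held 0.842 summits per 10 kb, and PRAS40 3.31, and these counts were not tested against chance. With summits given to the nearest gene at any distance, Polycomb and Trithorax genes had 17, against 4.19 by chance (adjusted permutation p = 0.015), and Notch pathway and E(spl) genes 23 against 4.12 (adjusted permutation p = 0.015).

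Known sequences split between promoter and other summits. The DRE was in 3.41% of 733 promoter summit windows and 0.175% of 1141 others, and Motif 1 in 3.14 and 0.0876% (Fisher's exact test, adjusted p = 8.4e-08 for each over 24 sequences). Unbound promoters held them about as often (DRE 2.86%, Motif 1 2.73%, exact paired test, adjusted p = 1 for each), so the split does not set bound promoters apart from others. Ohler motif 7 was in 6.82 and 2.45% (Fisher's exact test, adjusted p = 6.12e-05), and in 5.73% of unbound promoters (exact paired test, adjusted p = 0.957). The TATA box was in 6.96 and 4.21% (Fisher's exact test, adjusted p = 0.0438), and in 5.05% of unbound promoters (exact paired test, adjusted p = 0.583). The GC box (0 and 1.4%, Fisher's exact test, adjusted p = 0.00259), the Zelda site (0 and 0.876%, adjusted p = 0.0396) and the CTCF core (0 and 0.789%, adjusted p = 0.0497) were found only outside promoters among these windows. Unbound promoters did hold them: the Zelda site in 8 windows (1.09%, exact paired test, adjusted p = 0.0625), the CTCF core in 3 (adjusted p = 0.75) and the GC box in 1. The homeodomain core was in 16.6 and 18.5% (Fisher's exact test, adjusted p = 0.561).

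AATTAA, AAATTA and TAATTA were more frequent at summits. Base composition alone is argued against: with control windows with the same GC count, the lowest of the 3 ratios was 1.70 and the highest 2.22 (largest adjusted p = 1.09e-16, paired exact test). A hypothesis is that the tagged protein, or a partner, is recruited by such sequences. Stronger peaks held AATTAA more often (Spearman's rho 0.145, permutation p = 1e-05, the smallest possible), as this hypothesis predicts. That test was set after the fall of AATTAA with rank had been seen, so it gives the hypothesis no separate support. The relation is also slight, and stronger summits held less GC (36.5% at ranks 1 to 200, 39.9% at ranks 1001 to 1874). The protein that recognises these sequences may be the tagged one or any homeodomain protein at the same sites, and no biological explanation was tested with another sample.

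Almost no IDR summit lay in coding exons outside promoters. Coding sequence within promoters was counted as promoter. GC content alone is argued against, since 8.35% of GC-matched random positions (SD 0.562) fell in coding exons, above the upper limit of 0.297% for the summits. A caller or mapping that reports nothing there is argued against as well, since 12.6% of the 10000 weakest pooled peaks lay in coding exons, close to the 13.2% of chance. What stays open is that strong peaks may fall where chromatin is accessible, which no file used here measures, and that many weak peaks may be background.

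Ribosomal protein genes were bound at 40.2%. Signal at every ubiquitously expressed gene would bind other housekeeping lists as often, which was not seen. The proteasome, oxidative phosphorylation and transcription machinery lists had 9 of 220 genes bound (4.09%, exact 95% interval 1.89 to 7.62%). They are the lowest of the 7 lists compared, so they alone decide nothing. With translation, splicing, replication and mitochondrial ribosomal protein genes added, 32 of 425 were bound (7.53%, exact interval 5.21 to 10.5%). The lower limit for ribosomal proteins was 30.1%. Translation factors were highest of the 7 (14.8%), and splicing factors had the highest upper limit (29%). The lists were chosen after the results were seen, so this is a description and not a separate test. Signal at the most highly transcribed genes whatever the tagged protein was left open, as neither predicted outcome was met. AATTAA was in 7 of these 37 windows (18.9%), 30.6% of the 696 other promoter summits (Fisher's exact p = 0.145) and 3 of their own control windows (exact paired p = 0.344). Over 24 sequences none differed from the other promoter summits after adjustment: Motif 1 was in 5 of 37 and 2.59% of the others and the DRE in 5 and 2.87% (Fisher's exact test, adjusted p = 0.0757 for each), and TAATTA in 1 and 17.4% (adjusted p = 0.102).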
